A study of Mus musculus with 7 samples.

How the data were processed

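Dermal fibroblasts of female FVB/N mice were profiled after 8 days in culture, untreated or after 3 h of thapsigargin. The 7 libraries fell into 6 groups by their labels: RNA of untreated and of treated cells, CEBPB immunoprecipitation of untreated and of treated cells, and ATF4 immunoprecipitation of treated cells, with 1 library each, and bisulfite sequencing of untreated cells with 2 libraries. Per the submitters' processing notes, reads were processed with CASAVA 1.8.2 and Bowtie for RNA, with CASAVA 1.7, BWA and SAMtools for immunoprecipitation and with CASAVA 1.8 and Novoalign for bisulfite sequencing, on the mm9 build. Per the labels, RNA libraries were made from total RNA with a TruSeq kit. Versions of the other tools, the peak caller, the control used for peak calling and the program behind the expression values are not given in the sources used here.

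The RNA values were FPKM per gene entry with lower and upper confidence bounds and a status, as deposited by the authors; the 2 tables listed the same 23583 entries. The peak lists gave a position and a score per peak, as deposited by the authors, called per library. Scores had a median of 83.7 and reached 1334 in CEBPB peaks of untreated cells, 5.90 and 222 in CEBPB peaks of treated cells and 5.41 and 245 in ATF4 peaks, so scores ranked peaks within a list and were never compared between lists. Methylation was a percent per cytosine of a CpG, deposited by the authors as pooled values of both bisulfite libraries, without coverage; 18408731 CpGs had values on both strands. Entries marked as heterozygous in that file were left out. Without coverage no minimum number of reads could be set, and no interval was given for a methylation percent.

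RNA was described without p-values, because each condition had 1 library. The change of a gene was the difference of log2(FPKM + 1), which understates changes of low genes; a gene counted as higher or lower when it was at FPKM 1 or more in at least 1 library and differed by 1 or more. The depth was read from the confidence bounds, taken to lie 2 × FPKM divided by the square root of the fragments from the value. The implied fragments of entries with 3 to 200 of them were whole within 0.05 for 74.1% of 4194 entries of the untreated and 80.7% of 4277 of the treated library, and the implied totals were 53914231 and 78941806 fragments. These depths make counting error small against 2-fold changes for genes at FPKM 1 or more, whose median was 1757 and 2857 implied fragments. Intervals of ratios came from the same implied fragments. The treated library had 95 entries with a failed status and the untreated library 6, and each had 265 with low data.

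The named genes were fixed as the 15 largest increases and 10 largest decreases among expressed genes with 1 symbol, without numbered models, microRNA, small nucleolar RNA and ribosomal protein genes, up to 4 members with the largest change of each gene list, the most abundant member of each cell type list, and Atf4, Cebpb, Ddit3, Atf3, Cebpd, Cebpg, Dnmt1, Tet2, Actb and Gapdh; some genes that this rule takes are not reported here. The named peaks were the 5 highest scores of each list and the highest peak within 10 kb of 12 fixed genes. For each of 22 gene lists the median change was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins; lists with fewer than 3 expressed members got none. The lists covered stress response, metabolic, inflammatory, matrix, cell cycle, apoptosis, bZIP, DNA methylation and housekeeping genes, and markers of fibroblasts, keratinocytes, endothelium, macrophages and other leukocytes, melanocytes and Schwann cells, adipocytes, and muscle and pericytes. These rules, lists, 8-mers, tests and most alternatives were chosen before the data were examined.

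Gene entries were matched by symbol and overlap to GENCODE vM1, which covered 21567 of 22910 entries with 1 locus on chromosomes 1 to 19, X and Y (94.1%). Copies were sought by aligning 100-bp windows of transcripts, taken every 50 bp, to the genome with minimap2 2.31-r1302 and counting a window as copied with at most 3 mismatches elsewhere; 10496 of 19986 genes searched had no copied window. Junction density was the number of exon junctions per kb of coding transcripts. A junction-adjusted change was the log2 change minus the median of genes of like junction density, in 50 bins of genes at FPKM 5 or more in either library. It removes any change that goes with junction density, whatever the cause. This adjustment was added after the data were seen. A first measure, merged exons per kb, was replaced by junctions after its results were seen and is kept as an alternative.

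Overlap of peaks was 1 bp or more, with 100 random placements on the same chromosome as the level by chance. Peaks with any base within 1 kb of a gene start were placed there. The others were placed by their centre in coding exons, untranslated regions, other exons, introns or intergenic sequence. Genes were tied to a peak within 10 kb of their start and set against expressed genes that changed by less than 1.5-fold. Fisher's exact p over genes, which are not replicates, served only to sort the alternatives of these odds ratios. The 7 8-mers were sought within 100 bp of peak centres and in windows 2 kb to each side, with Fisher's exact test over peaks, two-sided, and Benjamini-Hochberg adjustment over 8-mers and lists; their odds ratios had 0.5 added to each count. Peaks on the mitochondrial genome had no such windows and were left out of that test. Peak methylation was the mean over its CpG cytosines, a peak was called methylated at 50% or more and unmethylated at 10% or less, and classes were compared by permutation tests over peaks with 100000 permutations and by Fisher's exact test. The level by chance came from 100 sets of random regions with as many CpG cytosines. An 8-mer's CpG took the mean of its measured strands. Promoters were the 500 bp on each side of a start, with 20 or more cytosines. Satellite-like peaks were those sharing 10 or more 14-mers with the tandem repeat at the start of the chromosome 9 sequence.

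The steps named here were tested on simulated data with known answers. The search for copies, the satellite-like peaks, the CpGs of 8-mers and the promoter test were not. Counts of the RNA simulation were drawn around 1 library with counting error only. The share of unaltered genes called there thus leaves out variation between libraries and cultures. For the count of higher and lower genes, among 11833 genes, 98% of genes made 3-fold higher and 82% of genes made 3-fold lower were recovered, 100% and 90% at 6-fold, and 0.0516% of unaltered genes were called. For the junction adjustment, a planted loss of −1.20 in 1817 genes became 0.04. That loss was an exact function of the junction density used by the adjustment, so its removal was fixed in advance. For the gene lists, 6.25% of random lists of 20 lay outside percentiles 2.5 to 97.5. For peak overlap, 1000 of 1000 planted overlaps were found. For peak methylation, 6.5% of null comparisons had p of 0.05 or less, in normal draws and not in peaks. For 8-mers, 100 of 100 planted were found. For genes near peaks, the odds ratio was 11.5 with planted and 0.977 with random peaks.

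Alternatives covered pseudocounts of 0.1 and 5, filters on low values, centring, junction density, genes without copies, an overlap of 50%, higher-scored peaks, equal numbers of peaks, chance by a shift of 10 kb, windows of 1 and 50 kb around starts, strata of expression, thresholds of methylation, peaks away from gene starts, peaks with 3 or more cytosines, CpGs measured on both strands, and peaks without satellite, mitochondrial and Y sequence. Those on centring on all expressed genes, junctions, merged exons, copies, estimate status, strands, satellite, mitochondrial and Y sequence, and on methylation among higher-scored peaks, were added after the data were seen, as were the expression strata of the promoter test, without which its odds ratio was 1.32 (1.15 to 1.50). Methylation alternatives used 10000 permutations. Coverage minimums and the bisulfite libraries apart were planned and not run, because the file holds pooled percentages without coverage. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.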

Results

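Dermal fibroblasts from female FVB/N mice, grown for 8 days, were measured with and without 3 h of thapsigargin. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER), disturbs protein folding there and brings about ATF4, a bZIP transcription factor of the integrated stress response. The 7 libraries comprised 1 RNA library of untreated and 1 of treated cells, chromatin immunoprecipitations of the bZIP factor CEBPB in untreated and in treated cells and of ATF4 in treated cells, with 1 library each, and 2 bisulfite libraries of untreated cells, whose CpG methylation was held as pooled percentages. The RNA tables listed 23583 gene entries in FPKM (fragments per kb of transcript, scaled to the fragments of the library). Of these, 11865 stood at FPKM 1 or more in the untreated library and 10915 in the treated library, and the confidence bounds of the entries implied 53914231 and 78941806 fragments in genes. The peak lists held 7317 CEBPB peaks of untreated cells, 7861 CEBPB peaks of treated cells and 10109 ATF4 peaks of treated cells. Methylation was listed for 38537328 CpG cytosines, with no number of reads, so the depth behind each percentage is unknown. Positions are given on the mm9 build with the GENCODE vM1 annotation. With 1 RNA library and 1 library of each immunoprecipitation per condition, no difference between conditions had a replicate check. Intervals cover counting error or, for bootstrap intervals of medians, the spread over genes, and none covers variation between cultures.

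The first comparison asked which transcripts differed after 3 h of ER stress. RNA of ER chaperones, of targets of the integrated stress response, of immediate early genes and of inflammatory cytokines was higher in the treated library, and RNA of collagens and of keratinocyte, melanocyte and Schwann cell markers was lower. Hspa5 (2:34627610-34632049), which encodes the ER chaperone BiP, stood at FPKM 354 in the untreated and 4978 in the treated library, a ratio of 14.1 (95% interval 13.9 to 14.2). Ccl2 (11:81849079-81850954), which encodes a chemokine that attracts monocytes, stood at 76.0 and 2118, a ratio of 27.9 (26.9 to 28.9). Col1a1 (11:94797584-94813170), which encodes a chain of type I collagen, stood at 6473 and 884, a ratio of untreated over treated of 7.32 (7.30 to 7.35), or a log2 change of −1.19 after the adjustment for exon junctions described below.

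On the log2(FPKM + 1) scale, 735 of 12207 expressed entries were higher by 1 or more and 3446 were lower by 1 or more, so increases made up 17.6% of these differences. Expressed entries are those at FPKM 1 or more in at least 1 library. The median log2 change over the 6551 entries at FPKM 5 or more in both libraries was −0.40. Centred on that median, 1345 entries were higher and 1932 lower, and increases made up 41.0%. Centred on the median of all expressed entries, −0.52, 1627 were higher and 1579 lower, and increases made up 50.7%, so the split depended on the genes used for centring. Set against genes with a like number of exon junctions per kb of coding transcript, 1475 were higher and 1257 lower of 11975. Increases then made up 54.0%. This comparison and the centring on all expressed entries subtract medians of much the same genes that are counted. A more even split thus follows in part from the method. Log2 changes are given on the authors' scaling, and the value set against genes of like junction density, called the junction-adjusted change, stands in parentheses beside genes of the lists where the sign turned or where only 1 of the values reached 1 in size.

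The change followed the structure of the genes. Across 8839 genes, Spearman's rho between log2 change and junctions per kb was −0.401 and Pearson's r was −0.390, while Spearman's rho with transcript length was 0.00606; genes are not independent replicates. Among genes without near-identical copies elsewhere in the genome, the median log2 change was 0.42 for the 64 genes without a junction (bootstrap interval 0.09 to 0.77) and −1.79 for the 173 genes with over 8 junctions per kb (−1.95 to −1.64). Cebpb and Bdkrb1 have no junctions, and Col1a1 has 9.50 per kb.

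**Figure D1:**
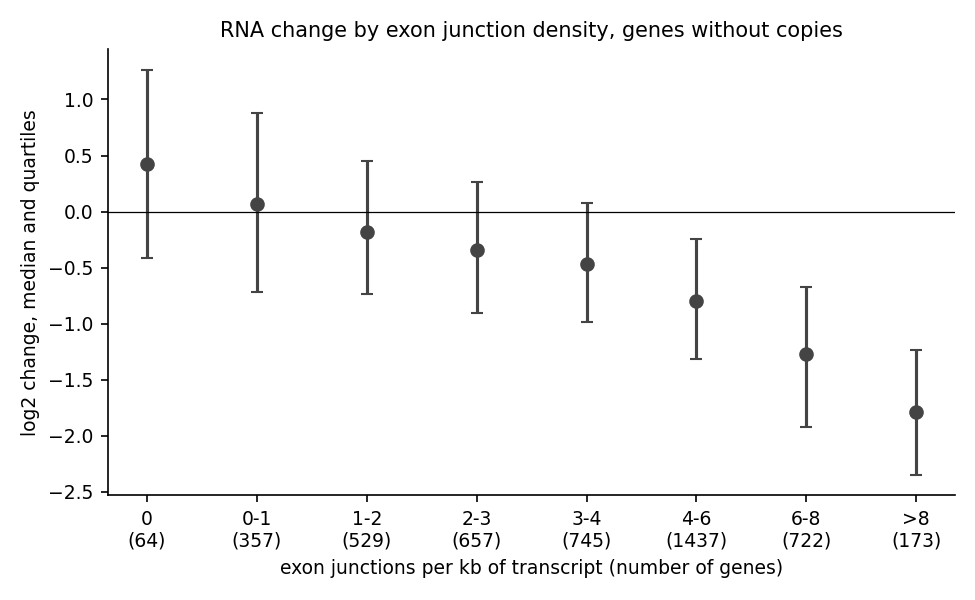
Median log2 change of thapsigargin over untreated RNA (vertical axis, log2(FPKM + 1) scale) against exon junctions per kb of coding transcript (horizontal axis, classes), for genes without near-identical copies, with bars for the quartiles. The median goes from 0.42 in genes without junctions to −1.79 in genes with over 8 junctions per kb.

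Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were higher as a group. Of 24 listed genes, all expressed, 15 were higher and 1 lower, and the list median of 1.18 lay at percentile 100 of 10000 random lists matched on expression, here and after junction adjustment. Atf4 itself (15:80085614-80087971) stood at FPKM 208 and 849, a ratio of 4.08 (4.03 to 4.14), and Ddit3 (10:126727849-126733344), which encodes CHOP, at 82.9 and 735, a ratio of 8.86 (8.58 to 9.15). Chac1 (2:119176978-119180062), which encodes a glutathione-degrading enzyme, stood at 16.8 and 168, a ratio of 10.0 (9.52 to 10.5), and Herpud1, a component of ER-associated degradation, at 55.6 and 471, a ratio of 8.46 (8.26 to 8.68). Asns, which encodes asparagine synthetase, had a log2 change of −0.16 and a junction-adjusted change of 0.63, so its sign depended on the scaling.

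ER chaperones and ER-associated degradation genes, which are read as the ATF6 and XBP1 arms of the unfolded protein response, had a list median of 1.09 (percentile 100), with 17 of 30 members higher and 2 lower. Besides Hspa5, log2 changes were 4.29 for Sdf2l1, 3.14 for Derl3 and 3.06 for Herpud1. Immediate early genes, which respond to calcium and growth signals within minutes, had a median of 1.38 (percentile 100), with 16 of 24 higher and 1 lower. Nr4a2 stood at 3.78, Maff at 3.73 and Myc at 3.32, the last with a failed estimate in the treated library. Fosl1 stood at 4.61, but Ccdc85b overlaps 68.1% of its exonic bases, so its value is uncertain.

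Cytokines, chemokines and NF-kB targets had the highest list median, 2.62 (percentile 100), with 21 of 25 expressed members higher and 2 lower. Il11 was listed at FPKM 0.667 in the untreated and 45.2 in the treated library, Cxcl2, which encodes a chemokine that attracts neutrophils, at 0.194 and 18.9, and Il6 at 1.63 and 30.7. Ccl20 was listed at 0 in the untreated and at 26.9 in the treated library. The bZIP family members able to pair with C/EBP or ATF4 had a median of 0.25 (percentile 100; junction-adjusted 98.9), with 13 of 40 higher and 6 lower. Log2 changes were 3.02 for Nfil3, 2.62 for Cebpb, 2.45 for Cebpd, 2.09 for Atf3 and 1.2 for Cebpg; Tmem189 overlaps 20.7% of the exonic bases of Cebpb.

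Genes of sterol synthesis and uptake had a median of 0.35 (percentile 99.98), with 4 of 20 expressed members higher and 2 lower. Cyp51, a demethylase of the sterol pathway, stood at 1.51, while Mvk, mevalonate kinase, stood at −1.25, or −0.04 after junction adjustment. Fdps at 1.45 and Idi1 at −1.83 have copies of 95.7% and 85.7% of their windows elsewhere in the genome, so both are uncertain. Amino acid transporters had a median of 0.04 (percentile 96.5; junction-adjusted 97.8), with 3 of 13 higher and 0 lower. Slc7a1, the cationic transporter, stood at 1.22, Slc3a2 at 1.16 and Slc7a11, the cystine transporter, at 1.11, while Slc7a3 stood at −0.97.

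Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include many ATF4 targets, had a median of −0.96 (percentile 1.64), with 10 of 20 lower and 0 higher, but a junction-adjusted median of −0.03 (percentile 28.9), with 1 lower and 2 higher. Qars stood at −3.19 (junction-adjusted −1.50) and Kars at −1.79 (−0.58), Mars at −1.91 (−0.57) and Vars at −1.76 (−0.42), while Gars stood at −0.90 with a junction-adjusted value of 0.29. Serine, one-carbon and proline synthesis had a median of −0.55 (percentile 43.9) and a junction-adjusted median of 0.42 (percentile 93.0). On the authors' scaling 3 of 15 expressed members were lower and 0 higher, and after junction adjustment 0 were lower and 4 higher. Mthfd2, the mitochondrial folate enzyme, stood at 0.91 (junction-adjusted 1.39), Mthfd1 at −2.45 (−0.87), Pycr1 at −1.48 (−0.28) and Shmt1 at −1.22 (−0.04).

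Collagens and other fibroblast matrix genes had a median of −1.37, at percentile 0 of the random lists, with 19 of 26 lower and 1 higher. After junction adjustment 7 were lower and 1 higher, and the median of −0.45 lay at percentile 0.16. Lum, which encodes the proteoglycan lumican and has few junctions, stood at −2.49 (junction-adjusted −2.56), Fbln1 at −2.39 (−1.62), Col3a1 at −2.41 (−0.73) and Col1a1 at −2.87 (−1.19). Reported substrates of IRE1-dependent decay, messages cleaved by the ER stress sensor IRE1, had a median of −1.19 (percentile 1.58; junction-adjusted 1.74), with 8 of 11 lower, but 3 lower and a median of −0.55 after junction adjustment. Among genes without copies the percentile was 4.29, no longer below 2.5. Scara3 stood at −2.51, Hgsnat at −1.92 (junction-adjusted −0.71), Pdk2 at −1.74 and Pdgfrb at −1.67 (−0.94), the last with a failed estimate in the treated library. Cell cycle and mitosis genes had a median of −1.01 (percentile 1.29), with 13 of 25 lower and 0 higher, among them Bub1b at −2.02, Ccnb2 at −1.58 (junction-adjusted −0.78), Ccnd3 at −1.49 and Cdc20 at −1.46 (−0.74). After junction adjustment 3 were lower and 1 higher, and the median of −0.29 lay at percentile 3.98, no longer below the threshold of 2.5, nor was that among genes without copies, 6.62.

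Markers of other cell types in skin cultures also differed between the libraries. Keratinocyte markers had a median of −1.80 (percentile 0), with 8 of 10 expressed members lower, among them Krt17 at −2.62, Krt14 at −2.31, Krt6a at −2.23 and Epcam at −1.96; Krt6a has copies of 59.1% of its windows. Markers of melanocytes and Schwann cells had a median of −1.80 (percentile 0.14), with 4 of 6 lower, among them Erbb3 at −3.04, Sox10 at −2.20 and Mlana at −1.39 (junction-adjusted −0.18). After junction adjustment 7 keratinocyte and 3 melanocyte and Schwann cell markers were lower, with medians of −1.19 and −1.33. Macrophage and leukocyte markers had a median of 0.01 (percentile 95.4), or 0.63 (percentile 98.2) after junction adjustment, and moved apart, with Cd14 at 2.83 and Fcer1g at 1.27, Cd74 at −4.44 and Lyz1 at −3.89. Lyz2, which encodes the macrophage lysozyme, was abundant in both libraries at FPKM 880 and 951. Fibroblast markers had a median of −0.95 (percentile 5.30), or −0.41 (percentile 2.90) after junction adjustment, with 6 of 15 lower and 1 higher, or 4 and 1, including Fap at −3.08 and Pdgfra at −1.72.

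Muscle and pericyte markers had a median of −0.59 (percentile 39.5) with 4 of 12 lower and 1 higher, but 0.12 with 0 lower and 1 higher after junction adjustment. Tnnt3 stood at −2.30 (junction-adjusted −0.62), Tnni2 at −1.32 (0.36), Acta2, which encodes smooth muscle actin, at −1.24 (−0.56), and Cspg4 at 1.43. Adipocyte markers had a median of −0.17 over 4 expressed members (percentile 78.6), or 0.41 after junction adjustment, with Fabp4 at −2.47, Cd36 at −0.60 (junction-adjusted 0.13), Lipe at 0.26 and Pparg at 0.82 (1.34). Of the endothelial markers 2 were expressed, Erg at −1.23 (junction-adjusted −0.55) and Eng at −0.90 (−0.03). Apoptosis regulators had a median of −0.39 (percentile 64.9), or 0.05 after junction adjustment, with Bmf at −2.77, Bax at −2.03 and the death receptor gene Fas at 1.67; Bcl2a1b at 0.98 (junction-adjusted 1.13) has near-identical copies. DNA methylation writers, readers and erasers had a median of −0.54 (percentile 52.2) with 5 of 14 lower and 0 higher, or −0.15 with 1 lower and 1 higher after junction adjustment. Tet3 stood at −1.41 (junction-adjusted −0.89), Uhrf2 at −1.29 (−0.93), Tet2 at 0.40, Dnmt1 at −1.67 (−0.33) after a failed estimate in the untreated library, and Tdg at −1.51 with copies of 88.4% of its windows. Housekeeping genes had a median of −0.57 (percentile 36.0; junction-adjusted median 0.26), with Pgk1 at −2.09 with copies of 97.1% of its windows, and Actb at −0.32, or 0.22 after junction adjustment.

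**Figure D2:**
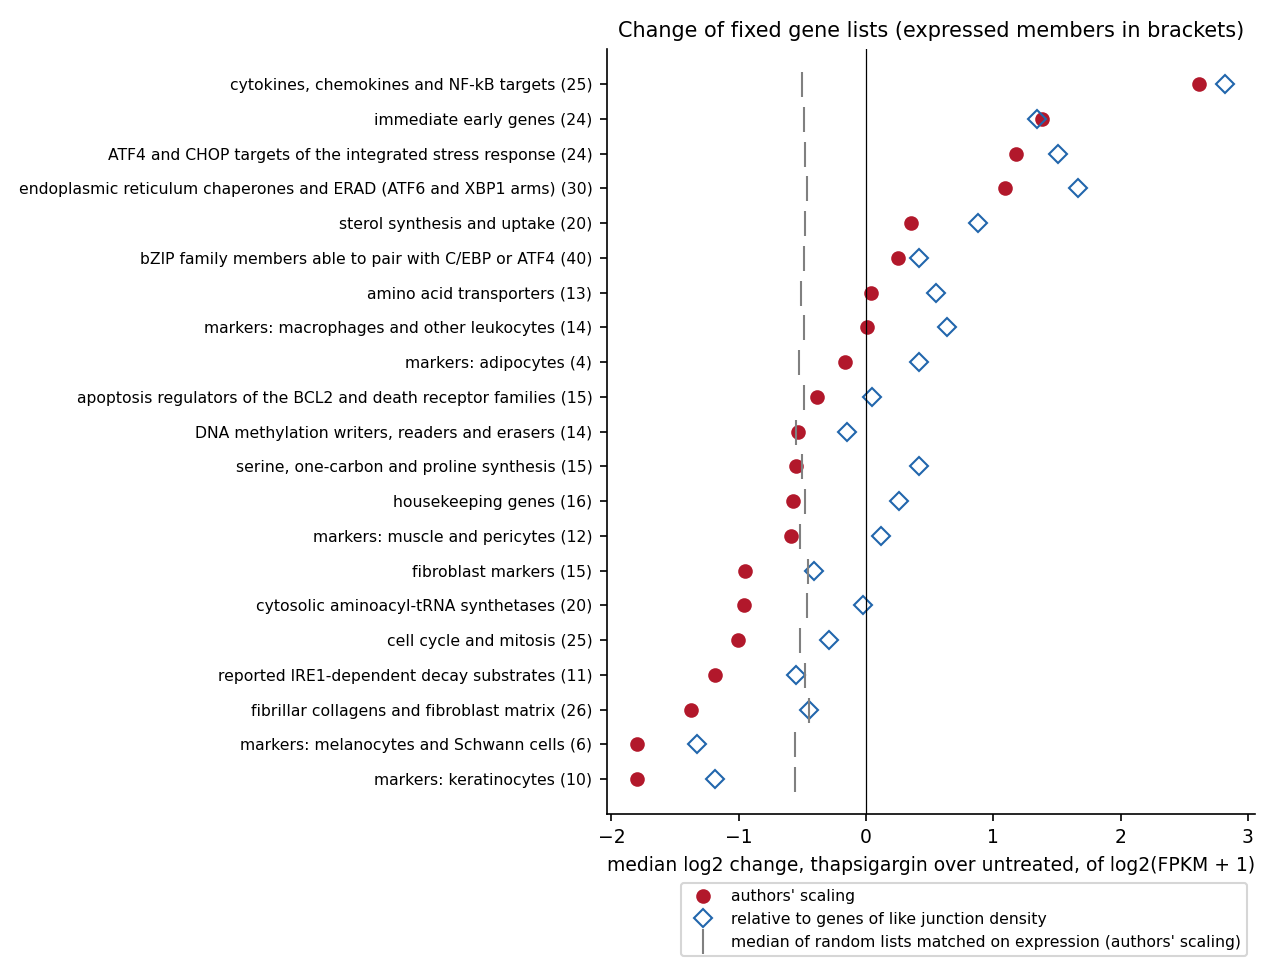
Median log2 change of thapsigargin over untreated RNA (horizontal axis, log2(FPKM + 1) scale) for each fixed gene list with its number of expressed members, on the authors' scaling (filled points) and set against genes of like junction density (open diamonds), with a grey bar at the median of random lists matched on expression. Cytokines lie highest at 2.62, and keratinocyte markers lie lowest at −1.80.

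The 15 largest increases were led by Rnd1, which encodes a small GTPase, with FPKM 0.352 and 78.9 and a log2 change of 5.89. Next came Snx22 at 5.03, whose exons Ppib overlaps over 20.4% of their bases, then Ccl20, Il11, Ccl2, Fosl1, Clec4e at 4.46, Rcan1 at 4.45, Phlda1 at 4.32, Sdf2l1, Ereg at 4.18, Rgs1 at 4.08, Bdkrb1 at 4.07, Cxcl2 at 4.06 and Rgs16 at 4.06. Rcan1, which encodes a calcineurin regulator, stood at FPKM 13.1 and 308.0. The 10 largest decreases included several genes with many processed copies: Gapdh was listed at 170.5 and 0.179 and Ppia at 544 and 0.0999, with copies of 85.2% and 59.1% of their windows, and Atp5g2 and Sumo2 have copies of 100% of theirs. Because these abundant housekeeping messages were listed near 0 in the treated library, their values are uncertain. Snhg1 was listed at 0 after treatment, and Rnaset2b and Atp6v0c-ps2 could not be searched for copies. Crip1, H2-Ab1 and H2-Aa, which encode a LIM protein and the chains of an MHC class II molecule, have no copies: Crip1 stood at FPKM 218.7 and 2.42, and H2-Ab1 and H2-Aa had log2 changes of −5.82 each. Of other genes without copies, a set added after these values were seen, Fxyd1 stood at −4.98, Ndfip1 at −4.32, Nckap1 at −4.28, Bicc1 at −3.86 and Ergic3 at −3.83.

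The second comparison asked where CEBPB was bound before and after thapsigargin and where ATF4 was bound. CEBPB peaks lay mostly away from gene starts in both states, and ATF4 peaks lay mostly at gene starts. Within 1 kb of a start lay 8.46% of CEBPB peaks of untreated cells (95% Wilson interval 7.84% to 9.12%), 6.54% of CEBPB peaks of treated cells (6.01% to 7.11%) and 66.1% of ATF4 peaks (65.2% to 67.0%). Introns held 43.3%, 39.1% and 9.82% of the peak centres, and intergenic sequence 45.6%, 49.7% and 13.9%. Median widths were 464, 172 and 266 bp. The scores of the lists are the authors' own values on different scales and served only to rank peaks within a list.

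Of the CEBPB peaks of treated cells, 1536 overlapped a CEBPB peak of untreated cells, 19.5% (18.7% to 20.4%), against a mean of 0.199% for positions placed at random. The share was 49.8% in the 1966 peaks with the highest scores and 2.95% in the 1965 with the lowest. An ATF4 peak overlapped 469 of the CEBPB peaks of treated cells, 5.97% (5.46% to 6.51%). The share was 0.187% at random positions and 0.560% after these peaks were shifted by 10 kb. ATF4 peaks overlapped 194 of the CEBPB peaks of untreated cells, 2.65%. Of the 449 ATF4 peaks that overlapped CEBPB in treated cells, 346 had no CEBPB peak in untreated cells. Without peaks in satellite, mitochondrial and Y sequence, 406 of the 449 remained. The list of untreated cells had 0 peaks in such sequence, and whether it was filtered there is not given. With 1 library each and lists called at different scores, these shares do not measure how much binding was gained or lost. Asking for an overlap of 50% of both peaks left 3.49% in place of 5.97% with ATF4. It was not informative between the CEBPB lists, because a peak of 172 bp, the median width in treated cells, cannot cover 50% of one of 464 bp, that in untreated cells.

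Of 7 fixed 8-mers, 6 occurred more often in CEBPB peaks of untreated cells than in windows 2 kb away. CGATGCAA, at 0.164% against 0.0957%, was not told apart from them (adjusted exact p = 0.232), and most peaks held none of the 7. Within 100 bp of the centre, TTGCACAA, a C/EBP site, occurred in 17.2% of CEBPB peaks of untreated cells and in 0.622% of windows 2 kb away. TTGCGCAA, the palindromic C/EBP site that holds a CpG, occurred in 3.91% against 0.0205% (Fisher's exact test over peaks, two-sided, adjusted p = 5.17e-132). In treated cells TGATGCAA, the composite site of C/EBP and ATF factors, was the most frequent of the 7 8-mers. It occurred in 7.66% of CEBPB peaks against 0.567% (adjusted exact p = 3.73e-194), while TTGCACAA occurred in 5.76%. Among the 500 with the highest scores, 21.2% held TGATGCAA and 13.6% TTGCACAA. CEBPB peaks listed only in treated cells held TTGCACAA in 2.07% and peaks listed only in untreated cells in 16.6% (adjusted exact p = 1.30e-185); TGATGCAA occurred in 6.13% and 4.84% (adjusted exact p = 0.00464). CGATGCAA occurred in 0.217% of CEBPB peaks of treated cells against 0.0955% (adjusted exact p = 0.0272), which was not past the threshold among the higher-scored peaks (adjusted exact p = 0.0979).

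ATF4 peaks held TGACGTCA, the cyclic AMP response element (CRE), in 1.23% against 0.149% of windows 2 kb away (adjusted exact p = 4.96e-33), TGACGCAA, which joins part of a CRE to part of a C/EBP site, in 0.475% against 0.0743% (adjusted exact p = 8.20e-12), and TGACGTAA in 0.297% against 0.0743% (adjusted exact p = 1.22e-05). TGATGCAA occurred in 0.564% of all ATF4 peaks against 0.545% (adjusted exact p = 0.913), but in 5.8% (4.07% to 8.21%) of the 500 with the highest scores. Where ATF4 peaks overlapped CEBPB peaks of treated cells, TGATGCAA occurred in 7.26%, against 0.259% of the other ATF4 peaks (adjusted exact p = 3.22e-28), and TGACGCAA in 4.76% against 0.280% (adjusted exact p = 5.07e-16). TGACGTCA occurred in 1.59% and 1.21% of these classes (adjusted exact p = 0.650). The C/EBP site TTGCGCAA, which holds a CpG, occurred in 0.139% of ATF4 peaks against 0.0198% of windows 2 kb away (adjusted exact p = 0.000189). TTGCACAA, which holds none, occurred in 0.158% against 0.520% (adjusted exact p = 9.76e-07). The windows were not matched on CpG number, so comparisons of ATF4 peaks with them do not separate a preferred site from base composition. A promoter test over strata of CpG number is given at the end. These p-values describe the peaks of 1 library each.

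**Figure D3:**
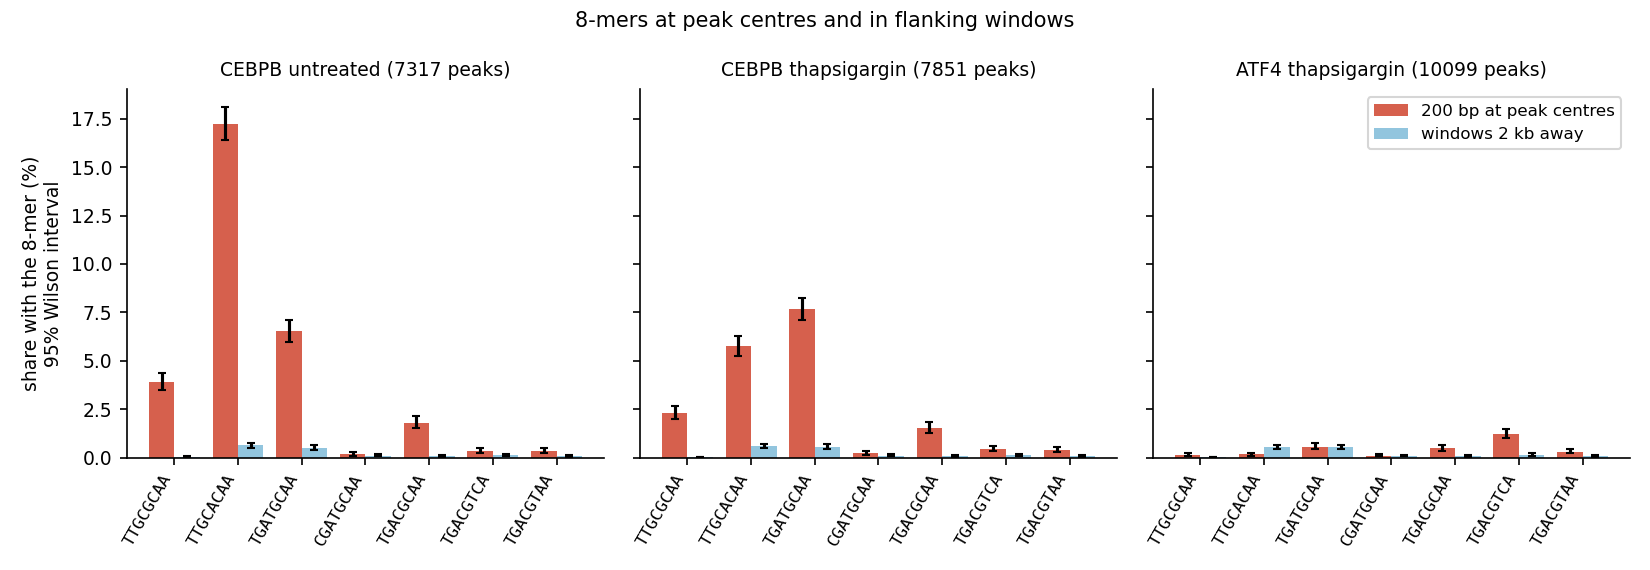
Share of peaks with each of 7 fixed 8-mers within 100 bp of the centre (percent, with 95% Wilson intervals) in the CEBPB and ATF4 lists, beside windows 2 kb away. TTGCACAA reaches 17.2% in CEBPB peaks of untreated cells and TGATGCAA 7.66% in CEBPB peaks of treated cells, while no 8-mer exceeds 1.23% in ATF4 peaks.

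The ATF4 peak with the highest score lay at 2:119176520-119177026, centred −205 bp from the start of Chac1, and overlapped CEBPB peaks of both states. It held TGATGCAA on the minus strand at 2:119176785-119176792, in the reference sequence TTCCCTGCCGTTGCATCACTCCTGCCAG, and TGACGCAA on the plus strand at 2:119176728-119176735, in GCCAGCAGCCTGACGCAATCTGACTCGC, with 0% methylation of that CpG on both strands. The peak at Asns (6:7642891-7643439, rank 4) covered an untranslated region, and the peak at Gars (6:54987800-54988340, rank 5) a coding exon at the gene start. Trib3 (2:152169560-152169992, rank 9), Herpud1 (8:96910016-96910609, rank 11), Ddit3 (10:126727373-126727759, rank 38), Cebpb (2:167515450-167515736, rank 79, in its untranslated region) and Atf3 (1:193006934-193007530, rank 287) had ATF4 peaks that overlapped CEBPB peaks of treated cells. Herpud1 held TGATGCAA at 8:96910217-96910224 and TGACGCAA at 8:96910199-96910206, and Ddit3 held TGATGCAA at 10:126727548-126727555. The ATF4 peak near Vegfa (17:46167425-46167673, in an intron) had no CEBPB peak, Slc7a11 had CEBPB peaks and no ATF4 peak within 10 kb, Il6 had a CEBPB peak only in untreated cells (5:30339368-30339738), and Col1a1 had none.

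The highest-scored CEBPB peak of untreated cells lay in an intron of Vmp1 at 11:86417180-86417765, centred −19813 bp from the start of the microRNA gene Mir21, and held TTGCACAA. Next in rank came peaks in a coding exon of Btbd19 (4:116792797-116793503), which held an unmethylated TTGCGCAA, and in introns of Emilin2 (17:71649752-71650214), Nt5c2 (19:46975683-46976419) and Htra1 (7:138086588-138087314). In treated cells the 4 highest CEBPB peaks, at 9:35112693-35113183, 15:74917061-74917499, 4:70039047-70039390 and 18:40467730-40468055, also overlapped ATF4 peaks, and none held any of the 8-mers near its centre. The peaks at ranks 1 and 3 carried the tandem satellite sequence of 234 bp period found where the assembled sequence of chromosome 9 begins. This property, chosen after the peaks were seen, was shared by 41 CEBPB and 45 ATF4 peaks of treated cells and by 0 CEBPB peaks of untreated cells, and 38 of the 41 overlapped ATF4 peaks. Whether such regions were filtered from the untreated list, whose scores are on another scale, is not given in the sources used here.

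**Figure D4:**
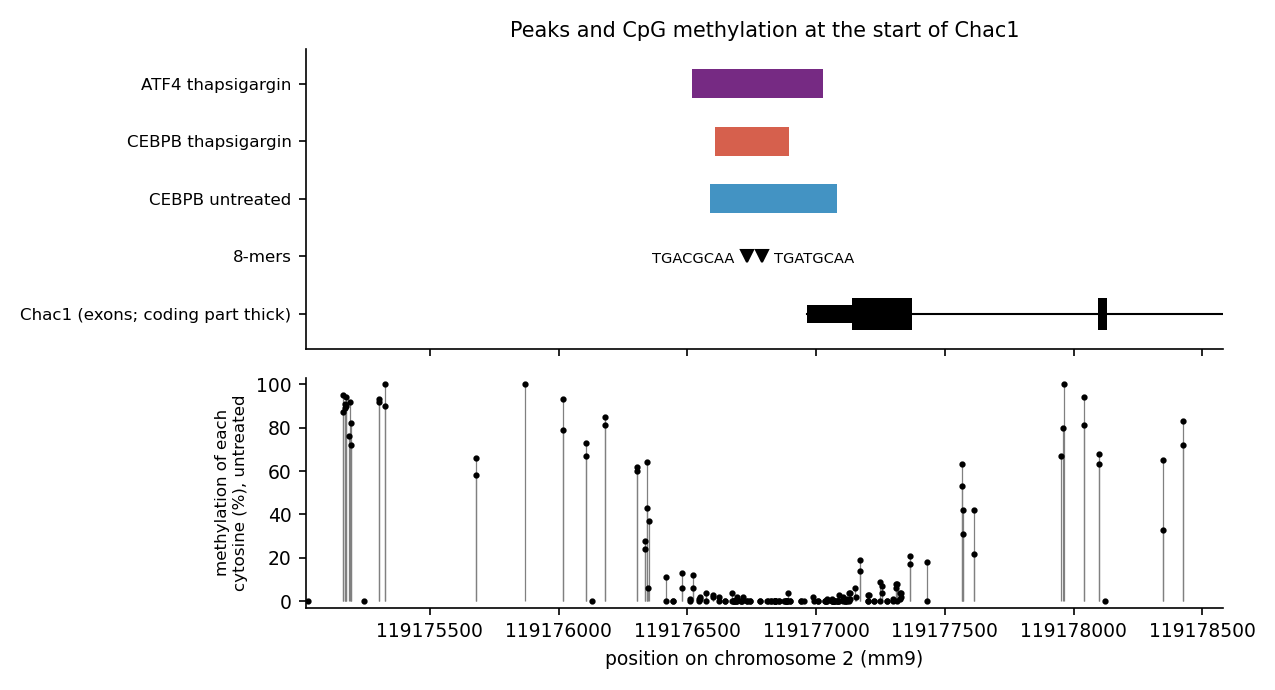
Region upstream of Chac1 on chromosome 2 (horizontal axis, mm9 position) with the gene, the CEBPB and ATF4 peaks, the composite 8-mers, and the CpG methylation of untreated cells (vertical axis, percent per cytosine). The ATF4 peak at 119176520 to 119177026 covers unmethylated CpGs with a mean of 0.746% over 63 cytosines.

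The third comparison asked whether genes that differed after thapsigargin had peaks within 10 kb of their start. Genes that were higher had CEBPB peaks of untreated cells more often than genes changed by less than 1.5-fold, 142 of 711 against 648 of 4994, an odds ratio of 1.67 (95% interval 1.37 to 2.05), and CEBPB peaks of treated cells in 14.6% against 10.8% (1.41, 1.13 to 1.77). ATF4 peaks lay near 51.8% of higher, 50.9% of lower and 58.5% of unchanged genes, with odds ratios of 0.761 (0.651 to 0.891) and 0.737 (0.675 to 0.804), and the former moved to 0.943 (0.841 to 1.06) after junction adjustment. Peaks of ATF4 and CEBPB together lay near 3.23% of higher and 2.12% of unchanged genes, an odds ratio of 1.54 (0.979 to 2.43), or 1.799 (1.29 to 2.51) after junction adjustment. Genes that were lower had CEBPB peaks of treated cells less often, 8.54% against 10.8% (0.769, 0.662 to 0.893), which moved to 0.975 within 50 kb. Genes are not independent replicates, so these ratios describe the lists, not the conditions.

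Peaks of ATF4 and CEBPB together, counted without a test over the fixed lists, lay near 10 of 24 targets of the integrated stress response (Asns, Atf3, Cebpb, Cebpg, Chac1, Ddit3, Eif4ebp1, Herpud1, Trib3 and Vldlr), 41.7%, against 1.88% of expressed genes. They lay near 7 of 20 aminoacyl-tRNA synthetases (Aars, Farsb, Gars, Iars, Mars, Tars and Yars), 35%, whose names, like those that follow, were chosen after the overlap was seen, and near 5 of 15 genes of serine, one-carbon and proline synthesis, 33.3%, including Mthfd2 and Shmt2. The lists share genes, among them Asns. The share was 15.4% for amino acid transporters, 2 of 13, but also 12.5% for housekeeping genes, 2 of 16. Of ER chaperones and degradation genes 23 of 30 had an ATF4 peak, 76.7% against 55.2% of expressed genes. Herpud1 had both factors together, which made 3.33% of that list against 1.88% of expressed genes. Of cytokines and NF-kB targets 0 of 25 had both together, which says little beside a share of 1.88%. A CEBPB peak of untreated cells lay near 13 of them, including Ccl2, Cxcl1, Il6 and Ptgs2, 52% against 12.8% of expressed genes. A CEBPB peak of treated cells lay near 5, 20% against 10.4%. Collagens and matrix genes had an ATF4 peak near 7 of 26, 26.9%, against 55.2% of expressed genes.

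ATF4 peaks followed expression in untreated cells. An ATF4 peak within 1 kb of the start was found for 12.8% (11.8% to 13.9%) of promoters of genes at FPKM 0.1 or less. For promoters of genes above FPKM 20 the share was 53.6% (51.9% to 55.2%).

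The fourth comparison asked how methylated CEBPB and ATF4 peaks were before treatment, since methylation was measured in untreated cells. The mean over all CpG cytosines was 66.4%, with 66.5% on autosomes and 65.3% on X, which has an inactivated copy in female cells. Promoters at 10% methylation or less made up 72.0% of autosomal promoters (71.3% to 72.7%) and 2.22% of X promoters (1.35% to 3.62%). Values of the strands of a CpG differed with an SD of 15.5 points over 18408731 CpGs.

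CEBPB peaks listed only in treated cells lay in methylated DNA more often than the other CEBPB peaks. A mean of 50% or more was found in 71.9% of the 4965 peaks listed only after thapsigargin with a measured CpG (70.6% to 73.1%), in 35.8% of 5538 listed only in untreated cells (34.5% to 37.1%) and in 14.4% of 1420 treated-cell peaks found in both states (12.6% to 16.3%). Mean methylation was 61.4% ± 27.1 (SD over peaks), 40.8% ± 22.2 and 25.2% ± 21.4. Random regions with as many CpGs averaged 67.0%, 68.7% and 64.8%. Peaks listed only after thapsigargin lay 20.6 points above peaks listed only in untreated cells and 36.2 points above treated-cell peaks found in both states (permutation test over peaks, two-sided, p = 1e-05 for each, the smallest that 100000 permutations can give). These tests compare peaks within 1 methylome, not cultures.

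ATF4 peaks lay in unmethylated DNA. Of 9533 ATF4 peaks with a measured CpG, 80.1% were at 10% or less (79.3% to 80.9%), and the mean over peaks was 13.04%, against 16.1% in random regions of like CpG number. ATF4 peaks that overlapped CEBPB were more methylated than the other ATF4 peaks, with a mean of 31.3% against 12.2% (permutation p = 1e-05), but random regions of like CpG number differed by more, with 41.6% against 15.03%. CEBPB peaks of treated cells that overlapped ATF4 were less methylated than those that did not, with a mean of 31.3% against 54.8% (permutation p = 1e-05) and 36.2% against 60.6% at 50% or more (odds ratio 0.368, 0.298 to 0.454). Random regions of like CpG number averaged 49.1% against 67.8%. Away from gene starts by more than 1 kb, the latter odds ratio was 0.813 (Fisher's exact test, two-sided, p = 0.133).

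**Figure D5:**
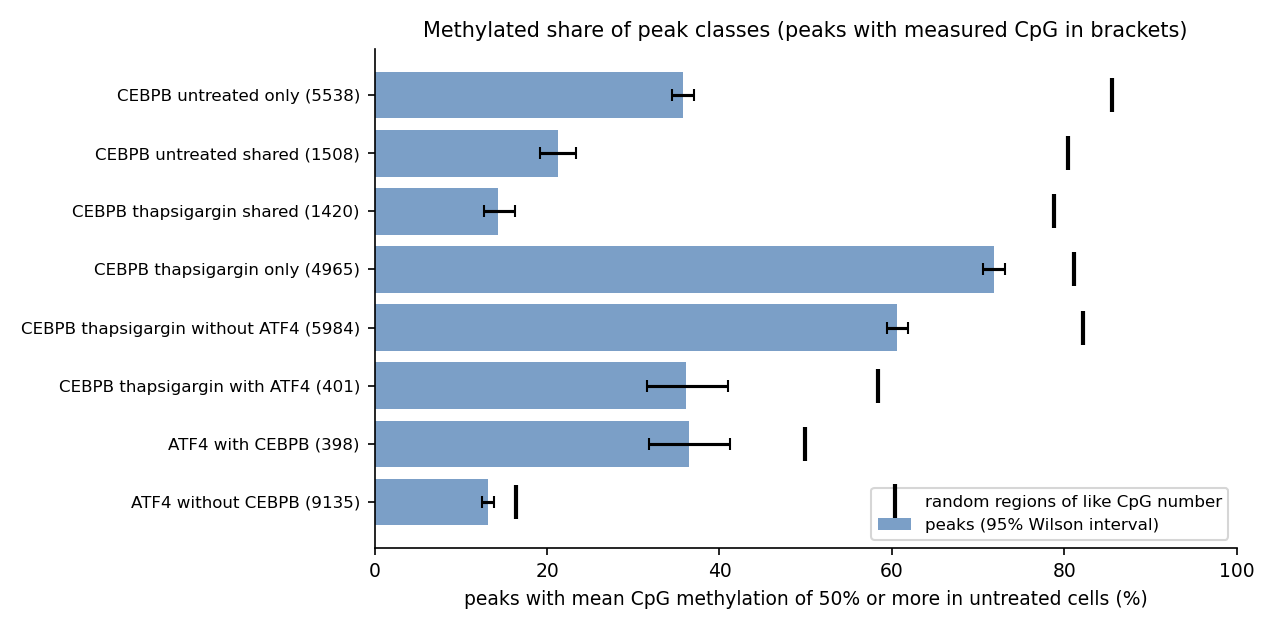
Share of peaks with a mean CpG methylation of 50% or more in untreated cells (horizontal axis, percent, with 95% Wilson intervals) by peak class, with black marks for random regions of like CpG number. Peaks of CEBPB listed only after thapsigargin reach 71.9%, and ATF4 peaks without CEBPB 13.1%.

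The CpGs inside the 8-mers were on average more methylated in CEBPB peaks than in ATF4 peaks, to an extent that differed between 8-mers. The CpG of TTGCGCAA averaged 54.2% ± 34.8 (SD) over 307 sites in CEBPB peaks of untreated cells and 80.9% over 1695 outside all peaks (permutation test over sites, two-sided, p = 1e-05, the smallest that 100000 permutations can give). In CEBPB peaks of treated cells it averaged 53.2% over 184 sites, of which 107 were at 50% or more. The CpG of TGACGCAA averaged 27.3% over 120 sites in CEBPB peaks of treated cells and 1.17% over 82 sites in ATF4 peaks, against 76.0% outside, and 0 of the 82 was at 50% or more. The CpG of TGACGTCA averaged 1.02% over 201 sites in ATF4 peaks against 63.3% outside. In CEBPB peaks of untreated cells it averaged 13.5% over 46 sites, of which 1 was at 50% or more. In those of treated cells it averaged 31.25% over 36 sites, of which 10 were at 50% or more. CGATGCAA lay in few peaks, with a mean of 42.3% over 18 sites in CEBPB peaks of treated cells against 71.2% outside (permutation adjusted p = 3e-05). It had 0 sites where CEBPB and ATF4 peaks overlapped. That 0 says little. Near the centre, 0 of 441 ATF4 peaks with CEBPB held it, with a Wilson upper bound of 0.864%, against 0.104% of the other ATF4 peaks. Counted the other way, 10.4% of methylated TTGCGCAA sites (9.05% to 11.9%), 60.2% of those over 10% and under 50% (50.1% to 69.6%) and 35.6% of those at 10% or less (29.1% to 42.7%) lay in CEBPB peaks of untreated cells, while of TGACGCAA sites at 50% or more 0 of 5571 lay in an ATF4 peak, with a Wilson upper bound of 0.0689%.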

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

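No test was planned for the values in this part, which were looked up after the peak lists and the methylation file were seen.

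The mitochondrial genome held 10 CEBPB peaks of treated cells, while the CEBPB list of untreated cells had 0 there, and it held 10 ATF4 peaks of treated cells. These peaks covered 3321 and 5918 bp, and 9 of the 10 CEBPB peaks overlapped the ATF4 peaks. They stood out as signal outside the chromosomes that the comparisons rest on, but whether such regions were filtered from the untreated list is not given in the sources used here, so the 0 need not be an absence of signal. No biological explanation was tested.

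Chromosome Y held 32 ATF4 peaks although the cells are labelled female. The highest of them ranked 104 among 10109, 0 lay within 1 kb of a gene start, and 0 carried the satellite sequence. The CEBPB lists had 0 peaks on Y. Methylation was listed for 1418 CpG cytosines on Y, with a mean of 57.8%. The listed cytosines covered 3.84% of the CpG cytosines of Y in mm9, against 78.8% on X and 89.1% over the placed chromosomes. Among RNA values, 0 of 13 gene entries on Y reached FPKM 1 in either library, and Xist, the RNA of the inactive X, stood at FPKM 19.5 and 15.7.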

How the results depend on the processing

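Settings on centring on all expressed genes, junction density, merged exons, copies, estimate status, strands of CpGs, satellite, mitochondrial and Y sequence, and methylation among higher-scored peaks were chosen after the data were seen. Of 309 alternative values, 262 counted as kept, 28 moved, 13 lost and 5 gained the threshold, and 1 reversed. Kept meant the same direction and side of the threshold, within the counting interval (overlaps) or within 1.5 times (gene counts and times chance). By the last rule 585 to 933 higher genes counted as kept. For gene lists it meant only the side of the percentile thresholds, so medians could turn sign. That of serine, one-carbon and proline synthesis went from −0.55 to 0.42 after junction adjustment and counted as kept. Odds ratios past the threshold in neither setting counted as kept whichever way they lay. Except where stated, the cause was not tested. For genes near peaks the threshold is an exact p over genes, which are not replicates and only sort the alternatives. The 30 alternatives on mean methylation of peak classes and the 12 on CpGs of 8-mers kept their direction and side of the threshold. No paired analysis was possible because the RNA and ChIP groups have 1 library each. Coverage minimums of 1, 5 and 10 and the bisulfite libraries apart were not run, because the file gives pooled percentages without coverage; unknown depth limits every methylation value.

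The count of 735 higher genes was 387 with a pseudocount of 5, 1345 centred on the median, 1627 centred on that of all expressed genes, 1475 against like junction density, 1559 against like merged exons per kb and 376 among genes without copies, where fewer genes were tested. The count of 3446 lower genes was 1736, 1932, 1579, 1257, 1216 and 1975 in the same order. Against like junction density the list percentiles were 97.8 for amino acid transporters and 98.2 for macrophage markers, now past the threshold, and 28.9 for aminoacyl-tRNA synthetases and 3.98 for cell cycle genes, no longer past it. Among genes without copies they were 7.88 for synthetases, 4.29 for reported IRE1 decay substrates and 6.62 for cell cycle genes, all no longer past it. Against like merged exons they were 33.5 for synthetases and 99.1 for macrophage markers.

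With an overlap of 50% of both peaks, 4.43% of CEBPB peaks of untreated cells overlapped those of treated cells in place of 20.9%, 4.12% the reverse in place of 19.5%, 3.49% of CEBPB peaks of treated cells overlapped ATF4 in place of 5.97%, and 2.71% of ATF4 peaks overlapped CEBPB in place of 4.44%; the first 2 are limited by median widths of 464 and 172 bp. Among the higher-scored peaks these were 27.2%, 25.3%, 7.43% and 5.43%. With equal numbers of peaks the second was 20.9% and the fourth 5.28%. Without satellite, mitochondrial and Y peaks the last pair were 5.39% and 4.05%. Against chance by a 10 kb shift, CEBPB peaks of treated cells overlapped those of untreated cells 61.4 times as often as chance in place of 98.1 and ATF4 peaks 10.7 times in place of 31.8, and ATF4 peaks overlapped CEBPB 10.7 times in place of 27.9.

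The odds ratio of lower genes with a CEBPB peak of untreated cells, 0.845, was 0.804 within 1 kb and 0.857 against like junction density, not past the threshold, and reversed to 1.05 within 50 kb. That of lower genes with a CEBPB peak of treated cells was 0.975 within 50 kb in place of 0.769. That of higher genes with ATF4 and CEBPB together was 1.49 within 50 kb and 1.799 against like junction density in place of 1.54, both now past the threshold. Against like junction density that of higher genes with ATF4 was 0.943 in place of 0.761, and that of lower genes with both together 0.590 in place of 0.596 with fewer genes. The odds ratio of methylated CEBPB peaks with against without ATF4 was 0.813 more than 1 kb from gene starts in place of 0.368. The odds ratio of CGATGCAA in CEBPB peaks of treated cells was 2.21 among the higher-scored peaks in place of 2.26, with fewer peaks. Mean CpG methylation was 67.3% over CpGs measured on both strands in place of 66.4%.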

Other observations

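The tests of background regions and of a lower threshold for CEBPB peaks were written down before their results were seen; all other tests of this part, and the antigen presentation and satellite features, were chosen afterwards.

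Several genes of MHC class II antigen presentation, picked after their values were seen and not tested as a list, stood lower in the treated library. H2-Aa and H2-Ab1, the chains of an MHC class II molecule, stood at FPKM 57.8 and 58.7 in the untreated library and at 0.0392 and 0.0550 in the treated library. Cd74, the invariant chain, stood at 143 and 5.61, H2-DMa at 9.63 and 1.33, and H2-DMb1 at 5.73 and 0.404, the last with copies of 42.3% of its windows. H2-Eb1 stood at 1.25 and 0.141, with a log2 change of −0.98 (junction-adjusted −0.28), and Ciita, the class II activator, at 0.629 and 0.00569. No class I gene looked at differed by 1 on the log2 scale: the genes H2-K1 and H2-D1 stood at 60.5 and 117 and at 195 and 305, with copies of 38.7% and 46.3% of their windows, while B2m, their partner chain, stood at 496 and 572 and Tap1, the peptide transporter, at 10.7 and 7.72, which turned from −0.43 to 0.18 after junction adjustment. Other macrophage genes went both ways. Csf1r stood at 20.5 and 36.5, Cd68 at 86.4 and 71.6, Ptprc at 4.41 and 3.26, and Tyrobp at 102.8 and 48.7. Cd14 stood at 14.8 and 111, Fcer1g at 77.6 and 189, and Itgam at 5.18 and 11.3. The authors' bounds of Itgam in the treated library ran from 0 to 18.3, so its value is uncertain. Lyz1 stood at 31.2 and 1.16, with copies of 33.3% of its windows. After junction adjustment Csf1r stood at 1.49 in place of 0.80 and Itgam at 2.12 in place of 0.996, Cd68, Ptprc and Tyrobp turned to 0.42, 0.54 and 0.27, and H2-K1 and H2-D1 stood at 1.62 and 1.53.

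Peaks with the satellite sequence ranked high in the treated lists; whether such regions were filtered from the untreated list is not given in the sources used here. They made up 4 of the 10 and 11 of the 100 highest CEBPB peaks and 2 of the 10 and 20 of the 100 highest ATF4 peaks, and 35 of the 45 such ATF4 peaks overlapped CEBPB peaks. Their mean methylation in untreated cells was 67.8% in each list. When all peaks of each list, with or without the sequence, were moved by 20 kb, 5 CEBPB and 6 ATF4 positions carried it.

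More genes were lower than higher in the treated library, and reads shared with near-identical copies are argued against as the whole cause, since genes without copies had a median of −0.64. The authors' scaling stays open for the split. Increases made up 41.0% after centring on genes at FPKM 5 or more in both libraries but 36.1% to 58.8% with other genes as the reference. Implied fragments per FPKM were 2.08 times as high in the treated library (median over genes), but fragments in genes were 1.46 times as high. The authors' scaling thus set treated values lower than scaling to fragments in genes would. Whether a different scaling or fewer fragments in genes lies behind this cannot be told from these values. Loss of reads across exon junctions is in line with the gap of −2.21 (−2.53 to −1.81) between genes with over 8 junctions per kb and genes without junctions. Such a loss may come from how reads were aligned or from less spliced RNA in treated cells. These cannot be told apart, because genes without junctions, at 0.42, allow either and reads in introns were not analysed here. Whether genes with few and with many junctions differed in regulation was not tested, and the adjustment would remove such a difference too. Median junctions per kb were 0.885 for immediate early genes and 6.57 for aminoacyl-tRNA synthetases. Junction loss is argued against as the whole cause of the lower fibroblast matrix genes. These were set against genes with a like share of 100-base windows that cross a junction. Their median then went from −1.37 to −0.60, and lower members from 19 to 10 of 26, but the median still lay at percentile 0.01. The treatment stays open there. With 1 library per condition, it cannot be told apart from other differences between the cultures, whose cell type markers also differed.

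CEBPB peaks listed only after thapsigargin lay in methylated DNA. Background regions are argued against as the whole cause, since 8.80% of the methylated peaks held one of the 8-mers, 5.56 times the 1.58% of windows 2 kb away, although most held none and a part may be background. A lower threshold that admits weak peaks stays open, because 50.2% of the 832 with the highest scores were methylated, 14.5 points above the 35.8% of peaks listed only in untreated cells and between the bounds set for either reading. Between classes of like rank the gap was wider, from 50.1% against 26.5% at the highest to 82.3% against 43.0% at the lowest scores. Equal ranks in lists on different scales need not be equal thresholds. Random regions of like CpG number were methylated in 81.1% for all peaks listed only after thapsigargin and in 85.6% for all listed only in untreated cells. The lowest-scored peaks listed only after thapsigargin thus lay near the level of random regions. Binding at the listed ATF4 peaks is argued against as the whole cause, since 4.06% of the methylated peaks overlapped one (3.46% to 4.76%), while ATF4 at sites outside that list stays open.

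ATF4 peaks lay at unmethylated promoters and seldom held a CRE or composite 8-mer. Calls made only for the CpG number and untreated expression of promoters are argued against as the whole cause. Promoters with an ATF4 peak held one of the 8-mers more often than others of like CpG number and expression. The odds ratio was 1.29 (1.13 to 1.47). The open state of promoters was not measured, so calls made for it stay open. A lower threshold that admits weak peaks is in line with the 8.33% of the 1020 highest-scored peaks that held such an 8-mer against 1.94% of the rest, 4.30 times as many. Recruitment of ATF4 to active promoters without its own site may add to this and was not tested.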
